A study of Oryza sativa Japonica Group with 3 samples.

How the data were processed

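Gene expression was measured by RNA sequencing in root tips of rice (cultivar Nipponbare), in a poly(A) RNA pool and a nuclear RNA pool. Per the labels, root tips of 1 cm were taken from seedlings 7 days old. The poly(A) pool came from a line expressing a tagged ribosomal protein L18, by capture on oligo(dT). The nuclear pool came from nuclei carrying a biotin-accepting tag on the nuclear envelope, captured on streptavidin beads, followed by degradation of ribosomal RNA. RNA pool, plant line and RNA selection therefore changed together. So did the strength of the growth medium per the labels (1 against 0.5), although the series' design text gives a single strength for all samples. Both kinds of library are described as random primed. The series states 4 biological replicates per pool, and every p-value rests on that statement. A sample of nuclei from the shoot base has no column in the deposited table and was not analysed here.

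The deposited table holds RPKM (reads per kilobase of gene, scaled by the reads of the library) for every library, computed by the authors. Per the submitters' processing notes, CASAVA 1.8, FastQC and TopHat2 2.1.1 were used with the IRGSP-1.0 genome; the read counter, its strand setting and the annotation release are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene, and reads shared by near-identical copies, can therefore not be told apart. It has 35694 lines for 35664 gene identifiers; 29 identifiers occur more than once with equal values and were counted once. Of these genes, 2473 were at 0 in all libraries. Gene symbols and descriptions are those of the table. The reference table pairs no identifier of this annotation, so coordinates, exon numbers and GC content were not analysed here.

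The RPKM of each gene are whole multiples of the value of 1 read, so reads, depths and gene lengths could be recovered. All 33191 genes above 0 came out as whole reads in every library, within 0.0001 of a read, and 99.79% of the recovered lengths lay within 0.02 nt of a whole number (3.98% at other depths). These lengths are those used by the counter, which need not equal the length of a gene model. On simulated RPKM, 99.4% of 19750 genes got their true reads, and with 1% noise 0.1% of genes came out whole. The poly(A) libraries held 29943165, 19411234, 28607640 and 28714155 reads on listed genes (replicates 1 to 4) and the nuclear libraries 1408613, 2287770, 1311039 and 1072511. One read on a gene of 1 kb was worth 0.033 to 0.051 RPKM in poly(A) libraries and 0.436 to 0.93 RPKM in nuclear libraries. Ratios for genes with 1 to 3 reads in a pool carry an exact binomial interval. For genes at 0 in a pool the bound sets that pool at 3 reads over its 4 libraries. Intervals and bounds cover counting error only.

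Differences between the pools were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on log2(RPKM + 1), over genes with a mean RPKM of at least 1 in either pool, two-sided, with Benjamini-Hochberg adjustment. A fold change is on that log2 scale and understates the change of genes with low values. Counts of genes use an adjusted p under 0.05 and an absolute log2 difference of at least 1; members of gene lists are called higher or lower at an adjusted p under 0.05 alone. Tested on data simulated with the depths of these libraries and a single spread beyond counting error per pool, 50 genes per fold size gave the following. Of genes changed 1.5-fold, 20% passed the adjusted p and 0% both thresholds. Of genes changed 2-fold, 66% and 28% passed, with 98% and 98% at 4-fold and 100% and 100% at 8-fold. The median recovered log2 differences were 0.54, 0.92, 1.78 and 2.68. Among 25932 unchanged genes, 35 passed the adjusted p and 21 both thresholds, 20 of them lower in nuclear RNA.

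The 28 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except those named as later. They cover cytosolic ribosomal proteins, organellar ribosomal proteins, translation factors, core histones, transposable elements, transcription factors, RNA splicing, chromatin regulators, protein kinases, NB-ARC resistance proteins, F-box proteins, proteasome subunits, pentatricopeptide repeat proteins, glycolysis and fermentation, mitochondrial respiration, heat shock proteins and chaperones, cell wall proteins, class III peroxidases, aquaporins, photosynthesis, seed storage and late embryogenesis, cell cycle and DNA replication, auxin and hormone response, annotated noncoding RNA, circadian clock genes, low oxygen response genes, root cell type and transporter genes, and shoot meristem genes. Members were matched by annotation words, or by identifier for the last 4. Lists with at least 5 tested members were tested against the other genes with limma's camera at a preset correlation of 0.01, with adjustment over 26 lists; camera with an estimated correlation and limma's fry stood beside it. On simulated data, 20 of 20 shifted lists and 0 of 180 others were called. The simulated genes varied independently, so this does not test calls of lists whose members vary together. The estimated correlation was 0.108 for cytosolic ribosomal proteins. Setting list members without nuclear reads to their bounds moved no list median (largest move 0).

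Named genes were the 12 with the largest log2 difference in each direction among genes past both thresholds. They needed a mean of at least 5 RPKM in the higher pool, no overlap between the libraries of the pools, and a functional annotation. This skipped 38 genes without one on the way to the 12 highest and 3 on the way to the 12 lowest. Added to these were up to 4 members per list with the smallest adjusted p, all members of the lists fixed by identifier, and genes related to the tags of the plant lines. These were all genes whose annotation names ribosomal protein L18, also as an L18/L5 domain or a plastid L18, or a Ran GTPase activating protein. They were compared by an exact two-sided permutation test. The relation to gene length was Spearman's rho across genes.

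Alternatives were other pseudocounts (0.1, 0.5), no filter and a stricter one (mean RPKM of 5), 4 other scalings, replicate number as a block, limma's trended and robust fit, array weights, treat, the other list tests, and leaving out each library in turn. The scalings were rescaling RPKM to an equal sum per library, median centring, quantile normalization, and rescaling without the 100 highest genes. Limma's voom on the recovered reads, thinning every library to the lowest read total, and taking off a trend on gene length were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table (1.17.8) were used as well.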

Results

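Transcripts were measured in the terminal 1 cm of rice roots in 2 RNA pools, poly(A) mRNA and RNA of isolated nuclei, with 4 libraries of each. The poly(A) libraries held 19411234 to 29943165 reads on listed genes and the nuclear libraries 1072511 to 2287770, a mean difference of 17.5-fold. Between 30990 and 31790 genes were above 0 in a poly(A) library and between 25575 and 27651 in a nuclear library. Pearson's r of log2 values ranged from 0.994 to 0.996 between poly(A) libraries, from 0.910 to 0.933 between nuclear libraries and from 0.769 to 0.820 between the pools. The most abundant gene in each nuclear library was OS08G0129800, at 17380 ± 1488 RPKM in nuclear RNA and 787 ± 36.3 RPKM in poly(A) RNA, where other genes were higher. The 10 most abundant genes took 2.16 to 2.25% of the reads in poly(A) libraries and 7.63 to 9.89% in nuclear libraries. All levels below are mean RPKM ± SD over the 4 libraries of a pool, and log2 differences are nuclear minus poly(A) with their standard error.

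The comparison of both pools asks which transcripts are over- or under-represented in the nucleus relative to the cell's polyadenylated mRNA. Nuclear RNA held less RNA of genes for ribosomes, respiration, glycolysis and the proteasome, and more RNA of genes for pentatricopeptide repeat proteins and NB-ARC immune receptors. CDT2 (OS06G0143100), annotated as similar to cadmium tolerant 1, fell from 122.8 ± 10.3 RPKM in poly(A) RNA to 0.596 ± 0.691 RPKM in nuclear RNA. The glycolytic enzyme gene TPI (OS01G0147900), for triosephosphate isomerase, fell from 519.8 ± 13.2 to 53.5 ± 6.44 RPKM, or 9.61-fold. SLR1 (OS03G0707600), the DELLA repressor of gibberellin signalling, rose from 54.0 ± 3.90 to 195.5 ± 14.9 RPKM, or 3.57-fold, and SHR1 (OS07G0586900), a GRAS transcription factor gene of the root, rose from 7.06 ± 0.473 to 34.4 ± 7.59 RPKM, or 4.31-fold.

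By limma, 6046 of 26928 tested genes were higher and 5697 lower in nuclear RNA at an adjusted p under 0.05 and a difference of at least 2-fold. Higher genes made up 51.5% of these, against 62.2% after rescaling RPKM to an equal sum per library, 63.9% after rescaling without the 100 highest genes, 49% with quantile normalization and 43.5% with median centring. The scalings therefore differ in which direction holds more genes. Without the requirement on fold, 8909 were higher and 8069 lower, together 63% of tested genes. The libraries of the pools did not overlap for 16450 genes (61.1%), where chance gives 2.9%. The median difference of all tested genes was 0.08 on the log2 scale and became 0.29, 0.33 and −0.08 under rescaling, rescaling without the 100 highest genes and median centring, so changes are relative to the other genes. At least 8-fold differences were found for 416 higher and 519 lower genes, but for 990 and 1358 with a pseudocount of 0.1. The higher count was 696 after rescaling, 760 after rescaling without the 100 highest genes and 1462 with voom on recovered reads. Of the tested genes, 219 had 0 reads in all nuclear libraries and 49 had 0 reads in all poly(A) libraries.

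The annotated gene with the largest rise was OS06G0647500, for a protein with a DNA/RNA non-specific endonuclease domain, at 1.28 ± 0.430 RPKM in poly(A) RNA and 6574 ± 1917 RPKM in nuclear RNA (log2 difference 11.47 ± 0.23, adjusted p = 3.17e-08). A transposon protein gene, OS06G0632300, rose from 0.302 ± 0.161 to 89.0 ± 18.4 RPKM. A RING/FYVE/PHD-type zinc finger gene, OS02G0192300, rose from 1.09 ± 0.289 to 124.5 ± 19.6 RPKM, and CIPK27 (OS09G0418500), a CBL-interacting protein kinase gene, from 0.1505 ± 0.0457 to 46.8 ± 11.8 RPKM. The other genes of the 12 highest were OS08G0274775 (similar to the phosphatidylinositol kinase family), OS08G0388150 (thaumatin-like), OS01G0825332 and OS01G0825166 (both similar to a splicing coactivator subunit), OS06G0495632 (similar to F-box), OS01G0594800 (similar to D-amino acid oxidase), OS04G0136016 (similar to growth-regulating factor 1) and OS02G0106966 (similar to an ATP-dependent helicase). These genes were short, from 381 nt (OS08G0274775) to 1283 nt (OS01G0594800) against a median of 1496 nt over tested genes, and need not encode whole proteins of these kinds. Their log2 differences ranged from 4.93 for OS02G0106966 to 5.72 for OS08G0274775. In poly(A) RNA, OS06G0495632 rested on 1 read, OS01G0825332 on 2 and OS01G0825166 on 3. From reads, the nuclear level of OS06G0495632 was 2280 times its poly(A) level, with an interval of 402 to 90700.

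Among the 12 lowest genes, CDT2 (OS06G0143100) had 3 nuclear reads against 8997 poly(A) reads, a ratio of 171 with an interval of 58.5 to 829. The glutathione S-transferase gene GSTF16 (OS03G0135200) was at 32.3 ± 1.96 RPKM in poly(A) RNA with 0 nuclear reads, at least 41.3-fold lower. The metallothionein gene MTI2B (OS01G0974200) fell from 99.7 ± 18.5 to 2.11 ± 2.45 RPKM and the salt-induced gene SALT (OS01G0348900) from 179.6 ± 118 to 3.88 ± 1.79 RPKM. A thionin gene, OS06G0509900, fell from 192.8 ± 72.0 to 4.96 ± 4.09 RPKM, and ARFA1E (OS01G0265100), for an ADP-ribosylation factor, from 229.8 ± 13.2 to 10.52 ± 9.60 RPKM. The rest of the 12 were OS03G0322500 (a zinc-binding protein similar to a protein kinase C inhibitor), OS12G0510900 (a LIM domain protein), OS11G0637501 (a membrane protein), OS05G0445500 (an acidic ribosomal protein), OS09G0568400 (ribosomal protein L40) and OS07G0615800 (an RNA polymerase subunit). Their log2 differences ranged from −5.37 for OS03G0322500 to −4.87 for OS07G0615800. All 12 were short, from 351 nt (OS07G0615800) to 881 nt (OS01G0265100), against a median of 1496 nt over tested genes. Shorter genes were relatively lower in nuclear RNA, and whether length accounts for part of these falls was not tested. Leaving out 1 nuclear library moved 4 of the 12 by over 1.5 times, with the call kept. ARFA1E (OS01G0265100, −5.01) had −4.07 without nuclear replicate 3, where it had 0 reads, and −5.60 without nuclear replicate 4. OS07G0615800 (16 nuclear reads) had −4.27 without nuclear replicate 1 or 4 and −5.60 without nuclear replicate 2. OS09G0568400 (29 nuclear reads, −4.94) had −4.18 without nuclear replicate 4, and OS11G0637501 (12 nuclear reads, −5.04) had −4.39 without nuclear replicate 1.

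**Figure D1:**
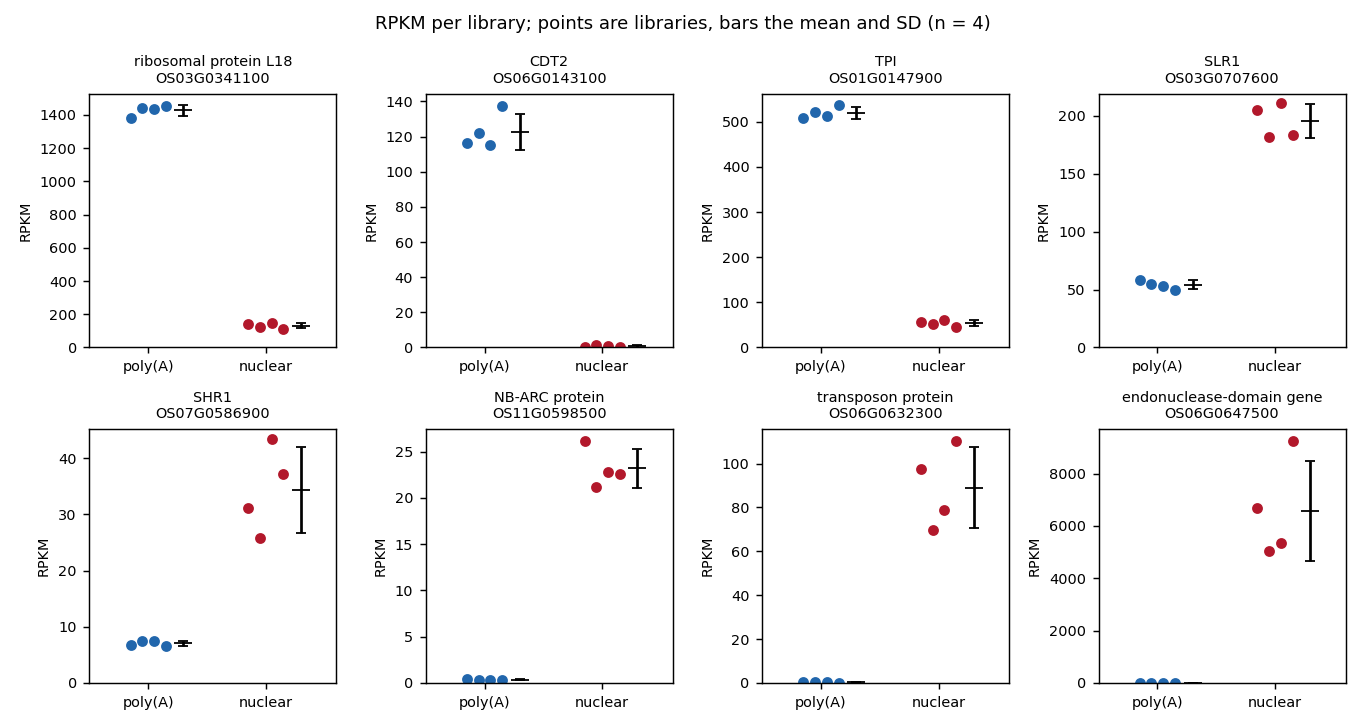
RPKM (vertical axis) of 8 named genes in the 4 poly(A) and 4 nuclear libraries; points are libraries and bars the mean and SD. The libraries of the pools do not overlap for any of the 8 genes: ribosomal protein L18, CDT2 and TPI lie lower in nuclear RNA and SLR1, SHR1, an NB-ARC gene, a transposon gene and OS06G0647500 higher. Transcripts of the tagged L18 in the poly(A) line could add to the poly(A) level of L18.

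The transcripts of the translation machinery were lower in nuclear RNA. Of 258 tested genes for cytosolic ribosomal proteins, 220 fell and 10 rose (221 and 11 adjusted over the list alone), with a median of −1.80 on the log2 scale (camera adjusted p = 5.66e-25). With an estimated correlation, 0.108 for this list, the camera adjusted p was 0.0351. The ribosomal protein L18 gene OS03G0341100 fell from 1428 ± 33.3 to 130.6 ± 16.3 RPKM, or 10.9-fold, and the L10 gene OS05G0169100 from 1020 ± 61.01 to 134.4 ± 8.69 RPKM, or 7.55-fold. The poly(A) line expresses a tagged L18, whose transcripts could add to the poly(A) level of OS03G0341100. The S15A gene OS07G0208000 fell 6.84-fold and the S11 gene OS07G0565100 fell 6.67-fold. For ribosomal proteins of plastids and mitochondria, 51 of 63 genes fell and 0 rose (51 and 0 adjusted over the list alone), with a median of −1.52 (camera adjusted p = 8.07e-10). By limma at an unadjusted p under 0.05, 0 of them were higher too. Genes similar to 50S proteins L20 (OS05G0528200) and L24 (OS11G0139100) fell by 3.62 and 3.25 on the log2 scale, and those similar to L33 (OS05G0513500) and L3 (OS01G0251100) fell by 2.14 and 1.65. Of 68 translation factor genes, 45 fell and 11 rose (46 and 11 adjusted over the list alone), with a median of −0.90. The camera adjusted p was 1.46e-06, and adjusted p = 0.0828 with an estimated correlation. Among them, an eIF5A gene (OS07G0597000) fell from 486.0 ± 13.7 to 56.9 ± 12.2 RPKM, EF1G (OS02G0220500), for elongation factor 1-gamma, fell 7.52-fold, and EIF3K (OS03G0182700) fell 7.72-fold.

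The lists of mitochondrial respiration, glycolysis and fermentation, and proteasome subunits were lower as well. Of 63 tested genes for mitochondrial respiration, 53 fell and 6 rose (53 and 6 adjusted over the list alone), with a median of −2.03 (camera adjusted p = 3.98e-13). The ATP synthase D chain gene OS08G0478200 fell from 569.3 ± 20.6 to 61.4 ± 10.6 RPKM, and both genes for subunit 8 of the cytochrome b-c1 complex fell, OS06G0177000 by 7.24-fold and OS06G0175900 by 6.70-fold. A gene for a Cmc1-like cytochrome c oxidase biogenesis protein, OS02G0560450, had 6.13 ± 0.383 RPKM in poly(A) RNA and 0 nuclear reads, at least 7.83-fold lower. Of 76 genes for glycolysis and fermentation, 51 fell and 8 rose (51 and 9 adjusted over the list alone), with a median of −1.11 (camera adjusted p = 3.04e-08). The enolase gene OS03G0248600 fell from 348.8 ± 20.1 to 46.6 ± 6.20 RPKM and a glyceraldehyde-3-phosphate dehydrogenase gene, OS02G0171100, from 158.6 ± 2.97 to 34.4 ± 0.517 RPKM. Of 52 genes for proteasome subunits, 43 fell and 4 rose (43 and 4 adjusted over the list alone), with a median of −1.60 (camera adjusted p = 1.4e-09). TT1 (OS03G0387100), for the alpha 2 subunit, fell 7.28-fold, RPT4A (OS02G0199900) fell 5.59-fold and RPN2B (OS04G0608500) fell 3.38-fold.

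Pentatricopeptide repeat, NB-ARC and F-box proteins were the 3 lists past camera that were higher in nuclear RNA. Of 332 tested genes for pentatricopeptide repeat proteins, which bind RNA in organelles, 251 rose and 10 fell (254 and 11 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 4.74e-15). OS01G0914600 of this list rose from 0.430 ± 0.112 to 20.8 ± 1.76 RPKM and OS12G0407900 from 3.56 ± 0.169 to 37.0 ± 3.60 RPKM. Of 263 NB-ARC genes, which encode intracellular immune receptors, 175 rose and 21 fell (177 and 22 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 1.4e-09). This median was 0.54 without a filter, 0.59 with the length trend taken off and 1.48 to 1.66 with a mean RPKM of 5, a pseudocount of 0.1 or voom. OS11G0598500 rose from 0.327 ± 0.0415 to 23.2 ± 2.11 RPKM and OS11G0213800 from 2.34 ± 0.370 to 35.6 ± 4.29 RPKM. Of 247 F-box genes, 124 rose and 30 fell (124 and 30 adjusted over the list alone), with a median of 0.66, or 0.26 without a filter. The camera adjusted p was 0.000438, and adjusted p = 0.0828 with an estimated correlation. D3 (OS06G0154200), the F-box protein of strigolactone signalling, rose from 9.18 ± 0.644 to 68.2 ± 7.23 RPKM, or 6.78-fold.

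Lists of nuclear functions were mixed. Of 56 core histone genes, 43 fell and 4 rose (43 and 4 adjusted over the list alone), with a median of −0.86 (camera adjusted p = 1.8e-07), or −0.50 with the length trend taken off. A histone H3 gene, OS03G0390600, fell from 269.7 ± 8.86 to 27.0 ± 7.20 RPKM, whereas a histone H2A gene, OS03G0144700, rose from 1.13 ± 0.245 to 12.9 ± 5.94 RPKM. Of 83 genes for RNA splicing, 37 fell and 21 rose (38 and 21 adjusted over the list alone), with a median of −0.59. The camera adjusted p was 0.0288, and adjusted p = 0.0739 with an estimated correlation. The call was also lost without a filter (adjusted p = 0.0552), with quantile normalization (0.0603) and without the 100 highest genes (0.0643), where the medians were −0.30, −0.52 and −0.23; after rescaling the median was −0.34. The small nuclear ribonucleoprotein G gene OS07G0608700 fell 8.73-fold; GLYI-11 (OS08G0191700), which fell 13.9-fold, carries both a splicing and a glyoxalase I annotation and encodes an enzyme of methylglyoxal detoxification. Of 60 transposable element genes, 28 rose and 11 fell (28 and 11 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.0579); the list passed without a filter (0.26), with a pseudocount of 0.1 (0.48), with a mean RPKM of 5 (0.81) and after thinning (0.46). The MuDR transposase gene OS07G0137500 rose 16.1-fold and a mutator-like transposase gene, OS09G0363200, 15.5-fold; TERT (OS12G0293100), which rose 16.4-fold, is the cell's telomerase and no transposon. Of 124 genes for chromatin regulators, 41 rose and 30 fell (40 and 30 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.716); a SET domain gene, OS07G0435900, rose 5.33-fold and a jumonji domain gene, OS12G0279100, rose 3.81-fold. Of 32 genes annotated as noncoding RNA, 11 rose and 8 fell (11 and 8 adjusted over the list alone), with a median of −0.07, a mean of 0.12 and a camera adjusted p of 0.996. Its members with the smallest adjusted p include a tRNA-pseudouridine synthase gene (OS01G0773000), a gene for an Hrd3 homologue of protein quality control (OS03G0259300) and SWEET1A (OS01G0881300), named after a sugar transporter, with log2 differences of 2.38, 1.41 and −1.90. The noncoding transcript OS06G0707800 rose from 0.517 ± 0.0600 to 3.54 ± 1.12 RPKM.

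For transcription factors and protein kinases, members moved in both directions. Of 669 transcription factor genes, 232 rose and 135 fell (229 and 132 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.316). A homeobox gene, OS01G0672201, rose from 2.77 ± 0.233 to 42.98 ± 4.06 RPKM and a MYB gene, OS06G0637500, from 35.4 ± 0.929 to 173.9 ± 13.7 RPKM. OS01G0938900 of this list, which fell 5.39-fold, encodes an alpha subunit of the nascent polypeptide-associated complex, a chaperone at the ribosome. Of 688 protein kinase genes, 287 rose and 180 fell (288 and 182 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.111). RLCK275 (OS09G0479200), a receptor-like kinase gene, rose from 23.9 ± 2.79 to 374.5 ± 55.5 RPKM. Of 201 genes for heat shock proteins and chaperones, 80 fell and 38 rose (80 and 37 adjusted over the list alone), with a median of −0.35, or −0.21 without a filter, −0.16 after rescaling, −0.14 without the 100 highest genes and −0.58 with a mean RPKM of 5. The camera adjusted p was 0.0161, and adjusted p = 0.0829 with an estimated correlation. A DnaJ gene, OS04G0549600, fell 7.38-fold, and a chaperonin Cpn60 gene, OS06G0616400, rose 5.37-fold. Of the 12 lists past camera at the preset correlation, 9 were lower and 3 higher in nuclear RNA. With an estimated correlation 8 were past camera, at adjusted p far closer to 0.05. These were 0.00345 for mitochondrial respiration and for glycolysis and fermentation, 0.0168 for organellar ribosomal proteins and 0.0207 for pentatricopeptide repeat proteins. They were 0.0351 for cytosolic ribosomal proteins, NB-ARC proteins and proteasome subunits, and 0.0452 for core histones.

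**Figure D2:**
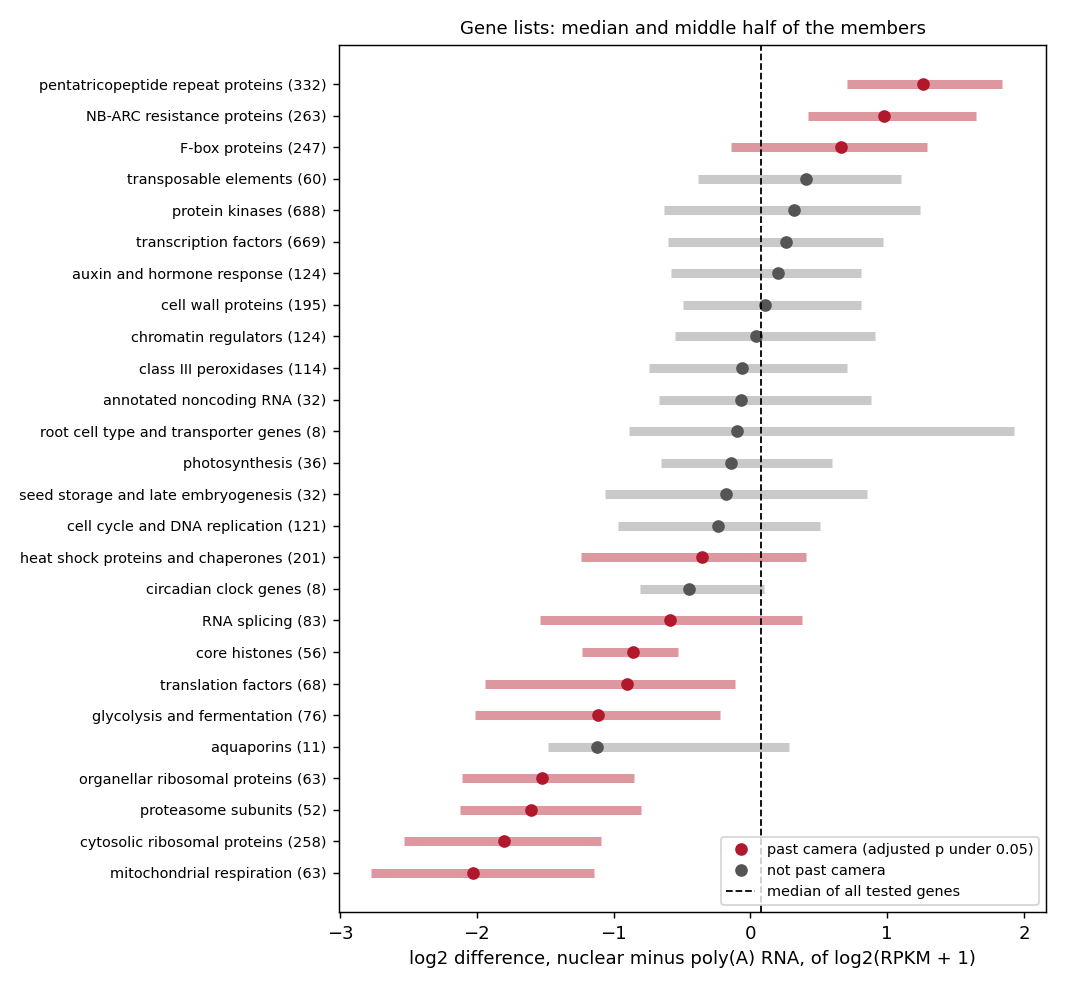
Median log2 difference (nuclear minus poly(A), horizontal axis) of each gene list as a point, with a bar from the first to the third quartile of its members and the number of tested members in parentheses. Red marks the 12 lists past camera, which run from mitochondrial respiration at −2.03 to pentatricopeptide repeat proteins at 1.26; the dashed line is the median of all tested genes, 0.08.

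Lists of root functions and growth did not pass camera. Of 195 cell wall genes, 63 rose and 44 fell (61 and 44 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.613). ND1 (OS12G0555600), a cellulose synthase-like gene, rose from 9.25 ± 1.00 to 138.7 ± 8.63 RPKM, and the expansin gene OS02G0268400 had 462 poly(A) reads and 1 nuclear read, a ratio of 26.3 with an interval of 4.7 to 1040. Of 114 peroxidase genes, 28 rose and 30 fell (28 and 29 adjusted over the list alone), with a median of −0.06 (camera adjusted p = 0.569). OS07G0676900 fell 2.78-fold and OS04G0656800 rose 3.04-fold; APX6 (OS12G0178100), which fell 3.59-fold, carries the symbol of an ascorbate peroxidase. Of 11 aquaporin genes, 6 fell and 3 rose (6 and 3 adjusted over the list alone), with a median of −1.12 (camera adjusted p = 0.108), but −0.56 with quantile normalization, −0.41 without a filter and −0.17 without the 100 highest genes. PIP1;2 (OS04G0559700) fell from 1058 ± 70.6 to 276.9 ± 62.5 RPKM and PIP1A (OS02G0666200) from 996.4 ± 65.7 to 397.9 ± 32.5 RPKM. Of 121 genes for cell cycle and DNA replication, 26 rose and 46 fell (25 and 45 adjusted over the list alone), with a median of −0.24 (camera adjusted p = 0.185). The median was 0 after rescaling and 0.04 without the 100 highest genes, but −0.42 with the length trend taken off, where the list passed (camera adjusted p = 0.0197). The phragmoplast kinesin gene OS04G0442800 rose 7.16-fold, and the kinesin gene SRS3 (OS05G0154700) fell 3.04-fold. Of 124 genes for auxin and hormone response, 39 rose and 30 fell (39 and 30 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.822). The gibberellin receptor gene GID1 (OS05G0407500) rose 2.73-fold and ERF54 (OS01G0657400) rose 4.5-fold; OS12G0623900, which fell 3.44-fold, encodes methionine synthase.

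Genes of the root's cell types and transporters were split. SHR1 (OS07G0586900) and SCR1 (OS11G0124300), transcription factors of the ground tissue, rose 4.31-fold and 3.81-fold, and the metal transporter gene IRT1 (OS03G0667500, ZIP10 in the table) rose 3.83-fold. LSI1 (OS02G0745100), the silicon influx channel, fell from 213.5 ± 25.8 to 69.3 ± 15.4 RPKM, NRAMP5 (OS07G0257200) from 12.3 ± 1.59 to 7.80 ± 1.44 RPKM, and the crown root regulator CRL1 (OS03G0149100) from 12.5 ± 1.21 to 5.41 ± 4.13 RPKM. The calls of CRL1 and NRAMP5 were lost after rescaling (adjusted p = 0.0624 and 0.0811), and that of CRL1 also on leaving out any library other than nuclear replicates 2 and 3 (adjusted p from 0.0502 to 0.0615). LSI2 (OS03G0107300) had a log2 difference of 0.40 ± 0.22 and QHB (OS01G0854500) of −0.75 ± 0.48, both not past the test, although LSI2 passed after rescaling (0.66, adjusted p = 0.0283) and QHB without nuclear replicate 3 (−1.23, adjusted p = 0.00715). Of the 8 tested genes of this list, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with a median of −0.10, a mean of 0.26 and a camera adjusted p of 0.716. HKT1;5 had 1 poly(A) read and 0 nuclear reads, and CASP1 was not analysed here.

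Clock and low-oxygen genes were included because harvest time and handling could move them. Of 8 clock genes, 4 fell and 2 rose (4 and 2 adjusted over the list alone), with a median of −0.45 (camera adjusted p = 0.473). GI (OS01G0182600), the GIGANTEA gene, fell from 92.0 ± 2.98 to 54.7 ± 11 RPKM, PRR1 (OS02G0618200) from 17.6 ± 1.16 to 8.80 ± 2.78 RPKM and ELF3-1 (OS06G0142600) from 5.96 ± 0.328 to 2.35 ± 1.21 RPKM. PRR73 (OS03G0284100) rose from 41.3 ± 1.05 to 59.99 ± 4.68 RPKM and PRR37 (OS07G0695100) from 21.0 ± 2.95 to 33.3 ± 3.45 RPKM, although the call of PRR37 was lost with array weights (0.61, adjusted p = 0.0536). PRR95 (OS09G0532400) fell by 0.53 on the log2 scale (adjusted p = 0.0432), a call lost with the replicate block (adjusted p = 0.0802), after rescaling (0.219) and on leaving out any library other than nuclear replicate 4 (0.0581 to 0.11). LHY (OS08G0157600) and PRR59 (OS11G0157600) had log2 differences of −0.37 ± 0.17 and −0.05 ± 0.13, not past the test; LHY passed with median centring (−0.52, adjusted p = 0.025) and without nuclear replicate 4 (−0.44, adjusted p = 0.0404). Of 4 tested low-oxygen genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone), with 0 higher at an unadjusted p under 0.05 by limma. ADH1 (OS11G0210300), ADH2 (OS11G0210500) and the haemoglobin gene HB1 (OS03G0233900) fell by 2.15, 2.43 and 1.98 on the log2 scale by limma, and PDC2 (OS03G0293500) had 88.4 ± 7.58 and 89.3 ± 9.91 RPKM. PDC1 and RAmy3D were below the filter.

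Lists of markers of other tissues did not pass camera. Of 36 tested photosynthesis genes, 7 rose and 7 fell (5 and 5 adjusted over the list alone), with a median of −0.14 (camera adjusted p = 0.553). PSBW (OS01G0773700), of photosystem II, had 4.46 ± 0.973 RPKM in poly(A) RNA and 0 nuclear reads, at least 5.66-fold lower. Of 32 genes for seed storage and late embryogenesis, 9 rose and 12 fell (9 and 12 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.502). LEA7 (OS03G0843300) fell from 176.6 ± 3.43 to 54.6 ± 8.58 RPKM, and OS08G0163600, with a late embryogenesis domain, rose from 2.096 ± 0.237 to 33.9 ± 9.89 RPKM. Of the shoot meristem genes, OSH1 had 0 reads in all libraries, OSH71 had 10 poly(A) and 0 nuclear reads, and OSH15 (OS07G0129700) had 1.47 ± 0.418 and 1.44 ± 0.123 RPKM. OSH15 was the 1 tested gene of its list, and 0 rose and 0 fell, also adjusted over the list alone; at an unadjusted p under 0.05 by limma the counts were 0 too (adjusted p = 0.997).

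The poly(A) line carries a tagged ribosomal protein L18, and genes whose annotation names L18 were compared between the pools. Since 220 of 258 cytosolic ribosomal protein genes fell, lower L18 genes in nuclear RNA do not check the labels. OS03G0341100 had the highest poly(A) level of the cytosolic ribosomal protein genes, 1428 ± 33.3 RPKM, and rank 56 in nuclear RNA. RPL18 (OS05G0155100) was at 561.5 ± 15.6 and 137.8 ± 22.4 RPKM, with ranks 25 and 48, and OS07G0674700 at 141.5 ± 5.04 and 55.3 ± 14.6 RPKM, with ranks 157 and 119. Each differed by an exact two-sided permutation test (p = 0.0286, the smallest that 4 against 4 libraries can give, and 0.0372 after adjustment over the 13 genes checked). Of the 13 genes, 7 were lower and 3 higher at that p. The 3 higher ones are annotated by an L18/L5 domain, as are several others, among them RPL5 (OS01G0896800). These counts are therefore not of L18 genes alone. A Ran GTPase activating protein gene, OS05G0543200, related to the nuclear envelope tag of the other line, was at 43.03 ± 1.52 RPKM in poly(A) RNA and 25.2 ± 4.66 RPKM in nuclear RNA. With 8069 genes lower in nuclear RNA, this fall does not show whether transcripts of the tag were present.

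Longer genes were relatively higher in nuclear RNA. Across the 26928 tested genes, which are not independent replicates, Spearman's rho between the log2 difference and gene length was 0.20, and between 0.171 and 0.200 for single nuclear libraries. In 5 groups of equal size from the shortest genes (6 to 863 nt) to the longest (2381 to 9536 nt), the median log2 difference went from −0.34 through −0.22, 0.08 and 0.11 to 0.46. Among the longest genes, 2588 were higher and 946 lower at an adjusted p under 0.05. Among the shortest, 1194 were higher and 2040 lower.

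**Figure D3:**
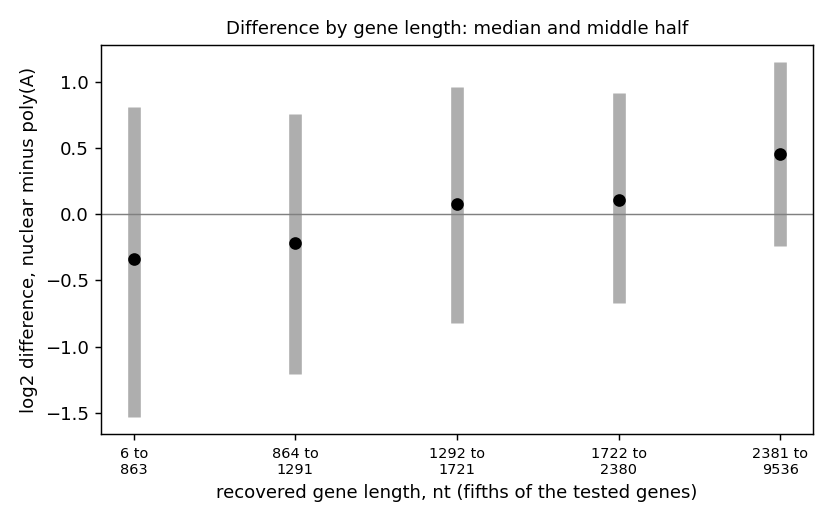
Median log2 difference (nuclear minus poly(A), vertical axis) in 5 groups of tested genes by recovered gene length in nt (horizontal axis), with bars from the first to the third quartile. The medians go from −0.34 in the shortest to 0.46 in the longest genes, and the bars overlap.

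Genes without a functional annotation were frequent among those higher in nuclear RNA. They made up 39.5% of tested genes, 49.7% of genes higher past both thresholds and 29.5% of genes lower past both thresholds. The highest of them, chosen after their values were seen, were OS06G0647900 at 5921 ± 1145 RPKM in nuclear RNA against 0.739 ± 0.274 RPKM in poly(A) RNA, and OS06G0648200 at 3093 ± 424 against 0.416 ± 0.107 RPKM.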

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

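Of the tests below, those of transgene transcripts, of few nuclear reads and of neighbouring gene models were chosen after the result was seen, as were taking off the length trend and thinning to 1 depth. In 267 checks, a library whose gap to the nearest other library of its pool exceeded the critical value of Dixon's test, as a share of the pool's range, was set apart. This marked 14 values, 7 in each pool, where chance marks about 1 in 20 groups, or 13.4 here.

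Poly(A) replicate 2 had 19411234 reads against 28607640 to 29943165 in the others, a gap of 0.873 of the range. The mean log2 level of the mitochondrial respiration list was 4.395 in nuclear replicate 4 against 4.469 to 4.478 (0.893). The zinc finger gene OS02G0192300 was at 0.667 RPKM in poly(A) replicate 4 against 1.19 to 1.31 (0.838). The F-box gene OS06G0495632 was at 0.0707 RPKM in poly(A) replicate 1 against 0 (gap of 1). The zinc-binding protein gene OS03G0322500 was at 8.43 RPKM in nuclear replicate 2 against 2.57 to 3.15 (0.844). The L10 gene OS05G0169100 was at 121 RPKM in nuclear replicate 3 against 138 to 139 (0.934). The organellar L24 gene OS11G0139100 was at 51.8 RPKM in poly(A) replicate 1 against 46.6 to 46.7 (0.993). The H2A gene OS03G0743400 was at 34.6 RPKM in nuclear replicate 1 against 50.9 to 52.0 (0.949). The MuDR transposase gene OS07G0137500 was at 25.2 RPKM in nuclear replicate 3 against 19.6 to 20.1 (0.89). The chromodomain gene OS07G0497100 was at 6.97 RPKM in poly(A) replicate 4 against 8.64 to 8.90 (0.881). The kinase gene RLCK275 (OS09G0479200) was at 19.7 RPKM in poly(A) replicate 4 against 25.1 to 25.4 (0.947). The expansin gene OS02G0268400 was at 0.513 RPKM in nuclear replicate 2 against 0 (gap of 1). LEA8 (OS05G0584200) was at 12.6 RPKM in nuclear replicate 1 against 16.5 to 16.9 (0.924). The kinesin gene SRS3 (OS05G0154700) was at 79.1 RPKM in poly(A) replicate 3 against 81.1 to 81.5 (0.833).

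Chance is argued against for the number of genes past both thresholds, but only as far as a rank of 1 in 35 allows. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many, with 11743 genes against at most 0. In the other splits, limma gave 96 to 1587 genes at an unadjusted p under 0.05, against 17972 in the real split. These splits put the difference between the pools into the spread within groups, which lowers their counts of genes. Their 0 therefore does not show what libraries without a pool difference would give. Chance cannot be excluded from the number of lists past camera alone: 8 of the 35 splits gave as many, with 12 lists in the real split and up to 14 in another. The 7 other splits with as many lists all kept 3 libraries of a pool together and so hold part of the difference between the pools; the 18 splits that mixed the pools evenly gave 0 to 2 lists.

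For the 12 shifted gene lists, gene length and read depth as the whole cause are argued against, since 12 of 12 kept call and direction with the length trend taken off and 12 of 12 at 1 depth. Their medians became 0.58 to 1.09 times as large without the length trend and 0.68 to 1.14 times at 1 depth, so both may account for part: core histones went from −0.86 to −0.50 and NB-ARC proteins from 0.98 to 0.59 without the length trend. A trend with expression level, taken as the mean over both pools, is argued against for 11 of the 12. Their medians lay outside the central 95% of 10000 random lists matched on that mean. The median of the core histones, −0.86, lay at percentile 2.75 of its random lists, so such a trend could account for it. The mean holds the nuclear level itself, so a trend with the poly(A) level alone was not tested. RNA selection method, plant line and medium cannot be told apart from the RNA pool, since 0 libraries of a pool were made with the selection of the other, and a shift that follows the pool itself stays open as an untested biological explanation.

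The L18 gene OS03G0341100 was far lower in nuclear RNA (log2 difference −3.45), and the poly(A) line carries an L18 transgene. Transcripts of the transgene could add to its poly(A) level, but 94.2% of the other 257 cytosolic ribosomal protein genes had a higher difference, short of the 95% set, and 15 had a lower one, so this cannot be told apart. With a trend on mean level within the list taken off, its residual lay below those of 89.1% of the others, but the mean level would hold transgene transcripts too, so a trend with level cannot be told apart from them. A biological difference between L18 and other ribosomal proteins was not tested.

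Few reads in the nuclear libraries are argued against as the cause of rises of at least 8-fold in nuclear RNA: of 435 to 455 genes this much higher in 2 nuclear libraries, 95.8 to 98.2% were at least 4-fold higher in the other 2, over the 6 choices of 2. The 416 genes at least 8-fold higher in all libraries together formed 40 pairs of neighbours in identifier order, where random draws gave a median of 6 and at most 18, so 1 transcript read over neighbouring gene models may account for part of them. The 519 genes at least 8-fold lower (476 to 594 without 1 library) were not put to the test on 2 nuclear libraries. In the simulation at these depths, 20 of 25932 unchanged genes were at least 2-fold lower past both thresholds. The simulation gave all genes of a pool 1 spread beyond counting error, taken from genes with ample reads. It therefore argues only against counting error alone as the cause of most of the 519 falls. A wider spread in genes with few reads was not simulated, and the size of single falls stays uncertain. These 519 genes formed 42 pairs (random median 10), a comparison added after the first count was seen. Neighbours can therefore not be told apart from clustering common to both directions. Of the 40 pairs, 38 had a member without a function and 1 shared an annotation, against 28 and 4 of the 42. Near the top gene OS06G0647500, the loci OS06G0647801, OS06G0647900 and OS06G0648200, chosen after their values were seen, had 2308, 5921 and 3093 RPKM in nuclear RNA; a common or nascent transcript there was not tested.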

How the results depend on the processing

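Voom, thinning to the lowest read total and taking off the length trend were chosen after seeing the data. Counts of genes past both thresholds stayed within 1.5 times the reported ones, between 5128 and 8019 higher and between 4519 and 6658 lower, except with treat, whose stricter null left 3164 and 2718 by construction. Leaving out 1 library gave 5787 to 6256 higher and 5372 to 5857 lower genes. No gene past both thresholds turned round, except 2 lower genes that were higher with voom. At least 8-fold higher genes numbered 990 with a pseudocount of 0.1, 696 after rescaling, 760 without the 100 highest genes and 1462 with voom. At least 8-fold lower ones numbered 1358 with a pseudocount of 0.1. With the replicate block, 6040 and 5713 genes passed, 6019 and 5670 of them the same, and 12 lists. Single values were followed through the alternatives for 102 genes, and some genes named above were not among them. The block ended the call of PRR95 and of no list or other gene followed. Deviations of libraries with equal numbers correlated at −0.005, 0.009, −0.048 and −0.042, within the −0.067 to 0.071 of unequal numbers. No pairing by number was seen, but counting error in the nuclear libraries could hide one.

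All 12 lists past camera kept their direction in every alternative run for lists, and 8 kept their call in all of these. The trended and robust fit, array weights and treat were run for genes only. Some medians moved by over 1.5 times: NB-ARC proteins to 0.54 without a filter, 0.59 with the length trend off, 1.51 with a pseudocount of 0.1, 1.48 at a mean RPKM of 5 and 1.66 with voom; F-box proteins to 0.26 without a filter; and core histones to −0.50 with the length trend off. Heat shock proteins moved to −0.21 without a filter, −0.58 at a mean RPKM of 5, −0.16 after rescaling and −0.14 without the 100 highest genes, and RNA splicing to −0.34 after rescaling. RNA splicing lost it without a filter (−0.30), with quantile normalization (−0.52), without the 100 highest genes (−0.23) and with an estimated correlation (−0.59). With the latter, translation factors (−0.90), F-box proteins (0.66) and heat shock proteins (−0.35) lost it too. Transposable elements passed without a filter (0.26), with a pseudocount of 0.1 (0.48), a mean RPKM of 5 (0.81), thinning (0.46) and fry (0.41). Fry, which does not compare a list with other genes, called 24 lists, adding transcription factors (0.26), chromatin regulators (0.04), protein kinases (0.32), cell wall proteins (0.11), aquaporins (−1.12), photosynthesis (−0.14), seed storage (−0.18), cell cycle (−0.24), hormone response (0.20), circadian clock genes (−0.45) and root cell type genes (−0.10). Cell cycle passed with the length trend taken off (−0.42). Of lists not past camera, the test's direction turned for noncoding RNA with a pseudocount of 0.1 (−0.09), no filter (−0.07), a mean RPKM of 5 (0.10), rescaling (0.15), without the 100 highest genes (0.19), fry (−0.07), thinning (0) and leaving out a library (−0.16 to 0.04). It also turned for photosynthesis with a mean RPKM of 5 (0.73) and the length trend off (0.19), peroxidases with quantile normalization (0.02) and chromatin regulators with the length trend off (−0.10). Apart from the estimated correlation, fry and treat, the cause was not tested.

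Spearman's rho with length was 0.23 with a pseudocount of 0.1, 0.213 with a mean RPKM of 5, 0.179 with quantile normalization and 0.194 to 0.205 without 1 library. Among genes matched by an L18 or Ran GTPase activating annotation, OS03G0694800 passed after median centring (−0.86, exact p = 0.0286). OS02G0689700 passed without nuclear replicate 1 (0.54, exact p = 0.0286, and 0.14 to 0.54 over all libraries left out). OS03G0828100 (−2.35 to −1.41), OS05G0543200 (−0.88 to −0.67) and OS10G0484400 (0.82 to 1.10) lost their exact p of 0.0286 without a poly(A) library, with fewer samples.

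Differences near 0 changed sign. OSH15 (OS07G0129700) had 0.01 and 0 with pseudocounts of 0.1 and 0.5, 0.18 after rescaling, 0.21 without the 100 highest genes, 0.20 with voom, 0.33 after thinning and −0.08 to 0.08 without 1 library. PRR59 (OS11G0157600) had 0.20 after rescaling, 0.24 without the 100 highest genes, 0 with voom, 0.10 after thinning and −0.12 to 0 without 1 library. PDC2 (OS03G0293500) had −0.15 after median centring, −0.02 with array weights, −0.01 with voom, −0.04 after thinning and −0.03 to 0.08 without 1 library. Of 2234 values of the genes followed through the alternatives, 2170 kept direction and call, 35 lost the call (11 of them with treat), 7 gained it and 22 turned. NRAMP5 also lost its call without the 100 highest genes, with array weights and after thinning, CRL1 without the 100 highest genes, and PRR95 without these and after thinning; LSI2 also passed without the 100 highest genes, with quantile normalization and with voom. The authors' own comparison was not run because the table holds none, nor were the alternatives for the shoot base. The nuclear libraries limit precision, since 1 read on 1 kb is worth up to 0.93 RPKM there.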

Other observations

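The annotation words tested here were chosen after the result was seen; the tests of identifiers and of spread were planned before theirs. Beyond the fixed lists, 128 annotation phrases were tested, and 10 held a larger share of genes higher in nuclear RNA than other annotated genes. In their share of lower genes 13 differed, with a larger share in 3 and a smaller one in 10. Of 96 cytochrome P450 genes, 39 were at least 2-fold higher and 3 lower, with a median log2 difference of 0.82 (Fisher's exact test, adjusted p = 3.88e-05 over 256 tests of 128 phrases). For all phrases, Fisher's test counts genes as independent, although genes of a family can vary together. Its p-values do not measure the spread between libraries. Of the 16932 genes counted as annotated here, 18.8% were higher and 24.4% lower. The rule for an annotation was looser here, and for the pairs of neighbours above, than for the named genes. It kept genes described only by a clone name, such as H0211B05. Of 32 aspartic protease genes of the A1 family, 19 were higher and 1 lower (median 1.17, adjusted p = 3.63e-05), and of 83 leucine-rich repeat genes, 34 were higher and 7 lower (0.72, adjusted p = 0.000151). MATE transporter genes had 12 of 26 higher and 0 lower (0.89, adjusted p = 0.02). Genes related to mitochondrial transcription termination factors had 12 of 28 higher and 1 lower (0.83, adjusted p = 0.0351). Of 85 UDP-glucosyltransferase genes, 25 were higher, which did not pass (adjusted p = 0.125), while the 2 lower ones were fewer than in other genes (adjusted p = 4.03e-06).

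The 3 phrases over-represented among genes lower in nuclear RNA had few members. Of 11 SNF7 genes, whose proteins sort membrane cargo, 8 were at least 2-fold lower and 0 higher (median −2.33, adjusted p = 0.016). Of 10 cysteine synthase genes, 7 were lower and 1 higher (−2.10, adjusted p = 0.0351), and of 10 chalcone and stilbene synthase genes, 7 were lower and 0 higher (−1.50, adjusted p = 0.0351).

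Identifiers not ending in 00 belong to gene models that were added between older ones, and such models may be richer in transcripts that stay in the nucleus. They made up 16% of tested genes, 22.5% of genes higher, 12.1% of genes lower and 43.5% of genes at least 8-fold higher in nuclear RNA. Over 10 groups of genes by mean level, the odds ratio of such an identifier among genes higher in nuclear RNA was 1.88 (95% interval 1.75 to 2.03). Among genes annotated by the looser rule it was 2.05 (1.75 to 2.41), and for genes lower in nuclear RNA, over all tested genes, 0.67 (0.62 to 0.74). Genes are not independent replicates, and RNA selection stays open as the source of the difference.

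Nuclear libraries varied more than poly(A) libraries, with a median SD of log2 values of 0.437 against 0.104. A candidate explanation is their lower read depth. Thinned to the nuclear read totals, the poly(A) libraries had a median SD of 0.264, or 60.4% of that of the nuclear libraries. Lower read totals alone thus did not give the whole difference. For the 2770 genes with a mean of at least 50 RPKM over both pools, the SD was 0.125 after thinning against 0.239 in nuclear libraries. Thinning matched read totals and not the reads of each gene, so counting error in genes with few nuclear reads may account for more of it. Other sources, such as the isolation of nuclei, were not tested.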
